A study of Mus musculus with 23 samples.

How the data were processed

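TCR transcripts were measured in 23 libraries of a syngeneic mouse model of Nras-mutant melanoma, treated with no drug, trametinib, BGB-283 or both drugs and sampled at D4 and D11. Per the labels, RNA was extracted with QIAGEN AllPrep and Ambion mirVana kits and libraries were made with the QIAGEN QIAseq Immune Repertoire RNA kit. The deposited table holds counts per chain, V segment, J segment and CDR3 amino acid sequence, not scaled between samples. The submitters' processing notes name GRCh38, a human assembly, for these mouse samples. The aligner, clonotype caller and filters are not given in the sources used here. The labels name TRA, TRB, TRG and TRD transcripts, but the table holds TRA and TRB alone.

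The values were tested for their unit. All 70466 values above 0 are whole numbers, and none is 1 or 2; the lowest is 3, found 5627 times. Values pile up at 20 (3655 times, against 804 at 19 and 509 at 21), at 40 (978, against 468 and 338) and at 60 (476, against 273 and 234). This is the form that reads summed over molecular identifiers holding 3 to 20 reads each would take, which is an inference from the values. An estimated number of molecules was therefore also used: each count divided by 20 and rounded up, a lower bound where molecules hold fewer reads. Among counts of 3 to 20, the share at exactly 20 was 33.5% ± 5.40 in control (n = 5), 24.0% ± 12.9 in trametinib, 16.8% ± 9.27 in BGB-283 and 4.99% ± 2.30 in combination libraries (n = 6 each), so equal counts are not equal molecules.

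Of 64710 entries, 274 with an unresolved CDR3 residue (0.0227% of counts) were left out and 64436 were analysed. Entries not starting with C (760) were kept. A value of 0 is given as listed at 0, since low values are absent from the table. Folds of segment shares against groups at 0 are given as bounds against 3 counts per library. All bounds hold for listed counts and do not cover the sampling of molecules. Log2 odds of lists are not bounds: in libraries at 0 their size depends on the 0.5 counts added, so bounds with every library at no fewer than 3 counts stand beside those of iNKT alpha against control where every treated library was above 0. Total counts per library ran from 70038 to 798622. Segment names were looked up among the gene symbols of the mouse reference annotation: 24 of 24 TRBV, 12 of 12 TRBJ, 41 of 41 TRAJ and 68 of 143 TRAV names matched, and the other 75 are joint names of copies the caller did not separate. No coordinates were used.

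TRB and TRA clonality is 1 minus the Shannon entropy over the log of the clonotype number. It and the clonotype number at equal counts were taken after thinning every library without replacement to 32534 TRB or 37504 TRA counts, as the mean of 100 seeded draws. The number of draws was raised from 20 to 100 after 20 draws had left 2 results at the edge of the threshold. In estimated molecules the depths were 1749 and 2013. The 10 largest clonotypes, clonotypes detected and CDR3 length used all counts. TRB counts per library were added as a measure after the data were seen. Log2 values of clonotype number and of counts were tested. List shares were tested as log2 odds with 0.5 counts added to each side.

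Treatment contrasts were combination, trametinib and BGB-283 against control and combination against trametinib and against BGB-283, and D11 was compared with D4. Each used a two-sided permutation test within strata on the mean over strata of the difference of group means, exact in every contrast, with 200, 400 or 80000 permutations. Benjamini-Hochberg adjustment covered the 6 contrasts of a measure, with a threshold of 0.05. Replicate numbers were not taken to pair libraries: in 0 of 28 pairs of groups was every same-number correlation over 0.1, so they entered no main test. Same-number correlations ran from -0.289 to 0.373 with a mean of -0.0182. Failing this rule does not exclude pairing. V and J usage was tested with edgeR's quasi-likelihood test on counts per segment, with 8 groups, segments kept by filterByExpr, TMM off and the chain total as library size. This left 24 TRBV, 118 TRAV and 12 TRBJ segments, with a biological coefficient of variation of 0.935, 1.32 and 0.576. The standard error is the log2 fold over the square root of F. Sharing was tested by 100000 permutations of group labels.

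Before the data were examined, 10 lists were fixed: iNKT alpha, MAIT alpha, the Vbeta8 family, iNKT partner betas, and 6 of gamma and delta segments. The last 6 have no entries, so they, gamma and delta usage and the gamma-delta share were not measured. The lists were to be adjusted over all 10 within a contrast; the values given first are adjusted over the 4 measured ones, which is a departure from that rule, and those over 10 stand beside them. MAIT alpha is given as counts alone, decided after its values were seen, and stayed in the adjustment. The segments named are those past the threshold, up to 10 in each direction, where fewer than 5 passed the 3 with the smallest unadjusted p as values, and members of the lists. Not every segment so listed is printed: the text keeps those with the smallest p. The clonotypes named are the 2 largest of each group by mean share, of which the text prints the highest, and the 5 found in the most libraries.

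Tests were tried on simulated data. The unadjusted p of the permutation test for combination against control was under 0.05 in 2% of 400 simulations with no shift. It was under 0.05 in 27.5% with a shift of 1 SD, 83% with 2 SD and 98% with 3 SD. With the adjustment over contrasts, which was not simulated, these shares could be lower but not higher. Thinned clonotype numbers lay within 0.148% of the exact expectation. In 40 simulations per setting of combination against control, a 4-fold change was called in 22.5% of changed TRBV, 0% of TRAV and 72.5% of TRBJ segments, and a 64-fold change in 72.5%, 36% and 100%. The changed segments were drawn from those below the median share and were only raised. Falls and changes of commoner segments were not simulated. Without change 0.625%, 0.0847% and 0.833% of segments were called. At a 64-fold change 7.07% of unchanged TRBV and 62.0% of unchanged TRBJ segments were called, since shares within a chain move together.

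Alternatives were thinning to a lower depth or none, CDR3 alone as clonotype, a Simpson-based index, the Jaccard index, TMM factors, DESeq2, no filter, each clonotype counted once, 5 counts added, a replicate block and leaving out each library. Added after seeing the data were estimated molecules, counts under 20 removed, both shallowest control libraries left out, TRAV11N included, TRAV families, 20 draws and adjustment over 10 lists. Tools were Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.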

Results

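T cell receptor (TCR) transcripts were sequenced from RNA of a syngeneic mouse model of Nras-mutant melanoma. The study concerns resistance to MEK inhibitors and T cell immunity against the tumour, so the TCR repertoire was read under 4 treatments. These were no drug (control), trametinib, an inhibitor of the kinase MEK, BGB-283, an inhibitor of RAF kinases, and trametinib with BGB-283 (combination). Each treatment was sampled at times labelled D4 and D11, and the labels do not say from which event the days are counted. There were 23 libraries in 8 groups, with 3 in each group except 2 in control D11. The table lists counts for the alpha (TRA) and beta (TRB) chains. A clonotype is a combination of V segment, J segment and CDR3 amino acid sequence, the CDR3 being the loop that differs most between T cells.

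Depth differed widely between libraries. Total counts ran from 70038 in control D11 replicate 1 to 798622 in combination D4 replicate 2, TRB counts from 32534 to 320420 and TRA counts from 37504 to 524431. In all, 35389 TRB and 29047 TRA clonotypes were found. The counts appear to be reads with several per molecule, so the number of molecules was estimated as the count divided by 20 and rounded up, a lower bound that assumes the same 20 counts per molecule in every library, and intervals on shares cover counting error only. Nothing in the labels says that the libraries of a group came from separate animals, so p-values measure only the spread between these libraries. Within a single day the smallest p for 3 against 3 libraries is 0.1, so each contrast pooled both days in an exact two-sided permutation test stratified by day. Its smallest p is 0.005, and adjusted p-values cover the 6 contrasts of each measure.

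Combination was compared with control to ask how treatment with both drugs acts on the repertoire. Combination libraries held many more distinct TRB clonotypes: 3355 ± 1473 (SD, n = 6) against 475 ± 238 (SD, n = 5), and all 6 lay above the highest control library at 749. With every library thinned to the same 32534 TRB counts, the numbers were 2557 ± 994 and 460 ± 224. Combination libraries also gave more TRB counts, 242013 ± 63952 against 85266 ± 62807. The 10 largest TRB clonotypes took 48.7% ± 12.03 of TRB counts in combination and 50.7% ± 6.98 in control libraries.

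The number of TRB clonotypes rose 6.93-fold (log2 2.79, p = 0.01, adjusted p = 0.02, exact permutation test, 6 against 5 libraries), with a log2 difference of 3.37 at D4 and 2.21 at D11. At equal counts it rose 5.53-fold (log2 2.47, p = 0.01, adjusted p = 0.02, exact permutation test). TRB counts rose 3.59-fold (log2 1.84, p = 0.005, adjusted p = 0.03, exact permutation test). The share of the 10 largest clonotypes did not pass over both days (-1.15 percentage points, adjusted p = 0.965, exact permutation test), a mean of opposite differences, -12.5 points at D4 and 10.2 at D11 (difference between days p = 0.05, adjusted p = 0.25, exact permutation test). TRB clonality, an index that grows as fewer clonotypes dominate, did not pass either (0.346 ± 0.0660 against 0.293 ± 0.0792, adjusted p = 0.46, exact permutation test), with -0.0105 at D4 and 0.131 at D11. Its direction is not settled, since the difference turned negative with a Simpson-based index (-0.0236) and in estimated molecules. Combination libraries had fewer counts per estimated molecule, and at 1749 estimated molecules per library the clonotype difference was 1.09 (703 ± 182 against 319 ± 109, adjusted p = 0.045, exact permutation test). Leaving out control D11 replicate 1 ended both clonotype calls (2.46 detected and 2.14 at equal counts, adjusted p = 0.05 each), leaving out combination D11 replicate 2 ended the call without thinning (2.55, adjusted p = 0.05), and leaving out any 1 of the 6 combination libraries ended that on TRB counts (1.69 to 1.96). Leaving out both shallowest control libraries ended all of these calls (2.24 detected, 1.93 at equal counts and 1.20 for TRB counts). Fewer libraries leave fewer permutations and a higher smallest p, so a call can end for that reason alone.

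**Figure D1:**
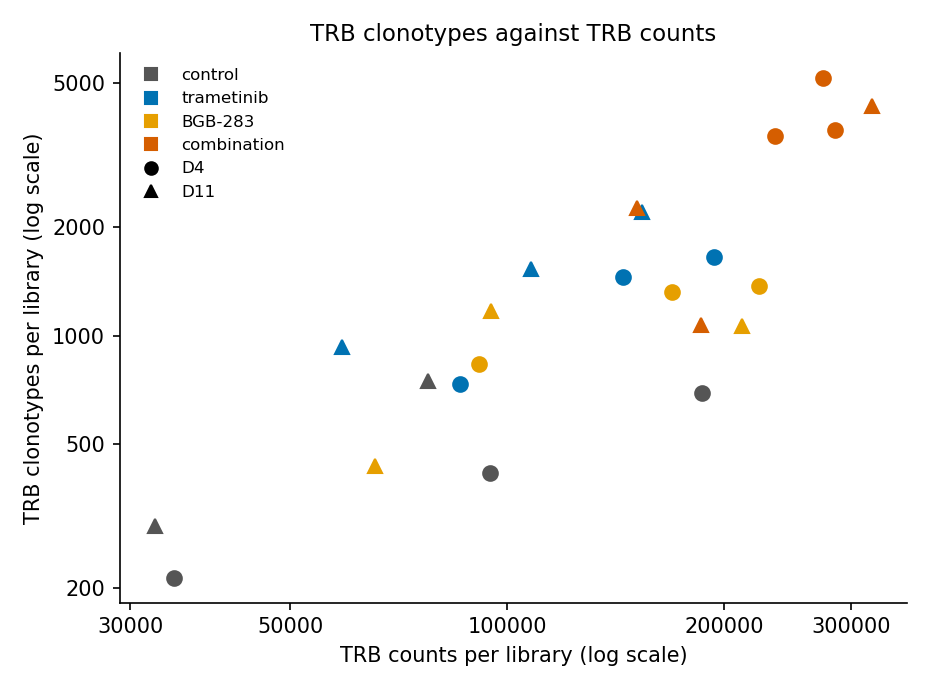
TRB clonotypes per library (vertical, log scale) against TRB counts per library (horizontal, log scale), 1 point per library, coloured by treatment and shaped by day. The 5 control libraries lie between 214 and 749 clonotypes, and the 6 combination libraries between 1074 and 5172.

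Trametinib was compared with control to ask what MEK inhibition alone does. Trametinib libraries were richer in TRB clonotypes, with 1417 ± 525 (SD, n = 6) against 475 ± 238 (SD, n = 5), and 5 of 6 lay above the highest control library. Their repertoires were also less dominated by large clonotypes. The 10 largest TRB clonotypes took 29.8% ± 8.82 of TRB counts against 50.7% ± 6.98, and all 6 libraries lay below the lowest control library at 45.1%. The largest single TRB clonotype took 9.61% ± 3.10 against 19.6% ± 8.28.

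Clonotype number rose 3.08-fold as detected (log2 1.62) and 2.98-fold at equal counts (log2 1.58), each with p = 0.005 and adjusted p = 0.02 in an exact permutation test of 6 against 5 libraries. At equal estimated molecules the rise was 1.05 on the log2 scale (672 ± 131 against 319 ± 109, adjusted p = 0.03, exact permutation test). The share of the 10 largest clonotypes fell by 20.1 percentage points (p = 0.005, adjusted p = 0.03, exact permutation test). TRB clonality was 0.204 ± 0.0634 against 0.293 ± 0.0792 (difference -0.0818, p = 0.045, adjusted p = 0.135, exact permutation test); it passed with a Simpson-based index (-0.103), in estimated molecules (-0.103) and without control D4 replicate 1 (-0.108). TRB counts were 124223 ± 49184 and did not pass (0.82, adjusted p = 0.135, exact permutation test). Leaving out control D11 replicate 1 ended both clonotype calls (1.29 and 1.25), and leaving out any 1 of the 11 libraries ended the call on the 10 largest clonotypes (-22.1 to -18.9 points, adjusted p from 0.06 to 0.1), since fewer libraries leave fewer permutations. Leaving out both shallowest control libraries ended these calls too (1.07 detected and 1.04 at equal counts), again with fewer permutations.

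**Figure D2:**
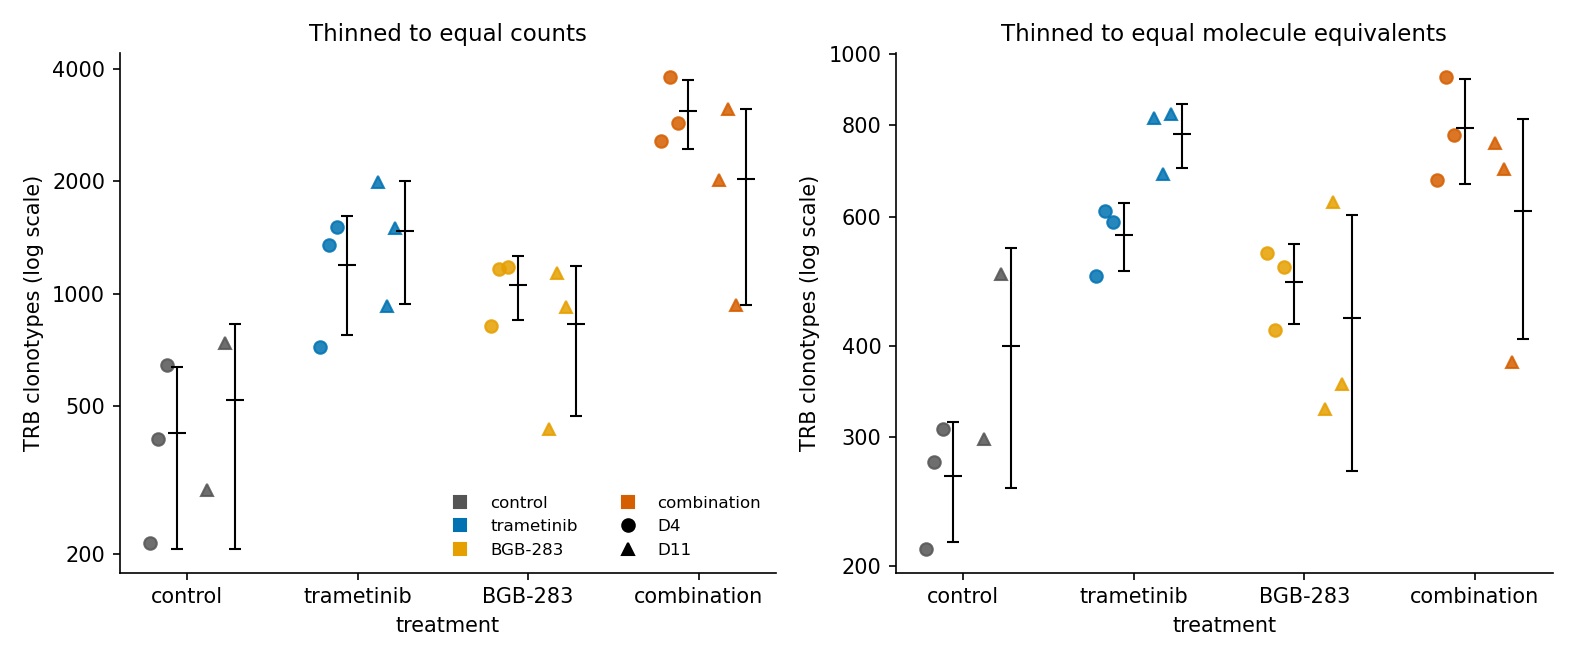
TRB clonotypes per library (vertical, log scale) by treatment and day after thinning to 32534 TRB counts (left) and to 1749 estimated molecules (right); points are libraries and black bars the mean ± SD of each group. At equal counts all 6 combination, 5 of 6 trametinib and 5 of 6 BGB-283 libraries lie above the highest control library.

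Invariant natural killer T (iNKT) cells are T cells with a nearly fixed alpha chain that recognise lipids on CD1d. Their canonical alpha CDR3, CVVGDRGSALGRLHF with TRAJ18, was listed at 0 in 3 of 5 control libraries and above 0 in 18 of 18 treated libraries. Its share of TRA counts was 0.103% ± 0.144 in control (SD, n = 5), 0.630% ± 0.570 in trametinib, 0.315% ± 0.247 in BGB-283 and 0.609% ± 0.300 in combination libraries (SD, n = 6 each). The V segments of beta chains that pair with it (TRBV13-1, TRBV13-2, TRBV13-3, TRBV29 and TRBV1) took 23.7% ± 3.55 of TRB counts in trametinib libraries against 13.9% ± 1.88 in control libraries, higher in 6 of 6 than in any control library. They took 17.7% ± 4.76 in BGB-283 and 23.4% ± 13.4 in combination libraries. These shares are far above those of the canonical alpha CDR3, so these V segments cannot stand for iNKT cells alone. A rise in them need not come from iNKT cells.

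Lists of segments were fixed before the data were examined, and 4 of the 10 could be measured, the others being gamma and delta chains with no entries. The iNKT alpha list, TRAV11 or TRAV11D joined to TRAJ18, was listed at 0 in 4 of 5 control libraries and above 0 in 6 of 6 trametinib, 5 of 6 BGB-283 and 6 of 6 combination libraries. For trametinib against control its log2 odds were higher by 4.64 and those of the partner beta list by 0.94, each with adjusted p = 0.02 over the 4 measured lists (p = 0.01 and 0.005, exact permutation test, 6 against 5 libraries). Adjusted over all 10 fixed lists, the family set in advance, both stood at 0.05 and did not pass; over the 6 contrasts the values were 0.06 and 0.03. With 4 of 5 control libraries at 0, the size of every iNKT alpha difference from control depends on the 0.5 counts added. With no library below 3 counts, the lowest value listed, that for trametinib was at least 2.69. Such bounds hold for listed counts and do not cover the sampling of molecules. Of the 5 partner segments 5 were higher and 0 passed in edgeR, over all 24 TRBV segments or adjusted over the list alone. TRBV13-1 to TRBV13-3, known as the Vbeta8 family, took 11.3% ± 2.86 against 7.47% ± 1.89 and did not pass (0.71, adjusted p = 0.0667, exact permutation test), except without trametinib D4 replicate 3 (0.85). Both list calls were lost without trametinib D11 replicate 2 (4.49 and 0.93) or trametinib D11 replicate 3 (4.54 and 0.89). They were also lost without control D11 replicate 1 (2.96 and 0.82) or without both shallowest control libraries. Each of these runs leaves fewer permutations. The call on iNKT alpha was lost as well with 5 counts added (2.26), in estimated molecules (1.88) or with each clonotype counted once (0.93).

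For combination against control 0 of 4 lists passed in exact permutation tests (iNKT alpha 3.85, at least 1.89 with no library below 3 counts, adjusted p = 0.30; partner betas 0.71, adjusted p = 0.56; Vbeta8 0.56, adjusted p = 0.56). Without combination D11 replicate 3, 3 of 4 passed (iNKT alpha, partner betas at 1.11 and Vbeta8 at 0.89, adjusted p = 0.0444 each). Leaving out other single libraries lowered the differences to as little as 2.17, 0.21 and 0.13 in the same order. Partner betas took 6.42% of TRB counts in combination D11 replicate 3 and 45.1% in combination D11 replicate 1. For BGB-283 against control 0 of 4 passed (iNKT alpha 2.28, with 1 of 6 BGB-283 libraries also at 0 and so no bound, adjusted p = 0.353; partner betas 0.39, adjusted p = 0.34; Vbeta8 0.09, adjusted p = 0.665). The caller placed 89.7% of the canonical CDR3's counts on TRAV11N, a near-identical segment that the list left out, and 9.85% on the joint name TRAV11V11D, so the copies are not separable here. With TRAV11N counted, a choice made after seeing the data, iNKT alpha passed for combination (6.10, at least 4.59 with no library below 3 counts, adjusted p = 0.02) against control in an exact permutation test. With TRAV11N and no library below 3 counts, the differences were also at least 4.45 for trametinib and 3.30 for BGB-283. The list for mucosal-associated invariant T (MAIT) cells, TRAV1 with TRAJ33, had counts in 2 libraries, 18 in combination D4 replicate 2 and 116 in combination D4 replicate 3.

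**Figure D3:**
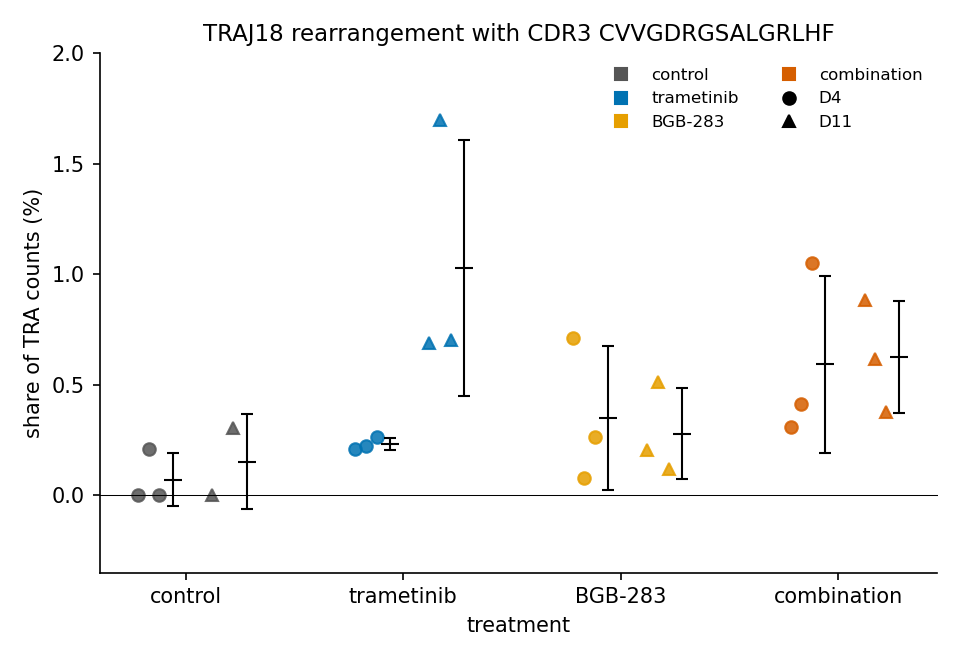
Share of TRA counts (percent) held by the canonical iNKT CDR3 with TRAJ18, by treatment and day; points are libraries and black bars the mean ± SD of each group. The canonical CDR3 is at 0 in 3 of 5 control libraries and above 0 in 18 of 18 treated libraries.

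BGB-283 was compared with control to ask what the RAF inhibitor alone does. BGB-283 libraries held 1031 ± 349 TRB clonotypes (SD, n = 6), with 5 of 6 above the highest control library. The 10 largest clonotypes took 50.2% ± 11.2 of TRB counts, with 2 of 6 libraries above the highest and 2 below the lowest control library. Among TRA segments, TRAV7N-4 took 0.898% ± 1.68 of TRA counts and was above 0 in 6 of 6 BGB-283 libraries and in 1 of 5 control libraries. TRAV14D-2 took 0.628% ± 1.04 against 0.0479% ± 0.0897 in control libraries.

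Clonotype number rose 2.23-fold as detected (log2 1.16, p = 0.035, adjusted p = 0.042, exact permutation test, 6 against 5 libraries). The difference did not pass at equal counts (1.07, p = 0.04, adjusted p = 0.054, exact permutation test) or at equal estimated molecules (0.50, adjusted p = 0.158, exact permutation test). TRB counts (0.98, adjusted p = 0.135), the 10 largest clonotypes (0.329 percentage points, adjusted p = 0.965, with -6.35 at D4 and 7.004 at D11, and negative in estimated molecules, with a replicate block and without both shallowest control libraries) and TRB clonality (0.0447, adjusted p = 0.522) did not pass in exact permutation tests. The call as detected ended with counts under 20 removed (0.86) and without both shallowest control libraries (0.61). It also ended without control D4 replicate 1 (0.94), control D11 replicate 1 (0.83), or BGB-283 D4 replicate 1 (1.27), 2 (1.10) or 3 (1.11). Leaving out BGB-283 D11 replicate 2 (1.03) or 3 (1.06) ended it as well. Runs that leave out libraries have fewer permutations. At equal counts the difference passed without control D4 replicate 3 (1.26), control D11 replicate 2 (1.40) or BGB-283 D11 replicate 1 (1.28), with a replicate block (1.02), and with 20 thinning draws (1.07, adjusted p = 0.048, exact permutation test), the number used before it was raised to 100.

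TRAV7N-4 and TRAV14D-2 rose with BGB-283 in edgeR (adjusted p = 0.0307 each). At D11 both control libraries were listed at 0. Against 3 counts per library, the lowest value listed, the listed share was at least 34.1-fold higher for TRAV7N-4 and at least 36.8-fold for TRAV14D-2. These bounds hold for listed counts only. The control D11 libraries held 2013 and 6717 estimated TRA molecules, and a segment missed among so few could have a larger share. At D4 the ratios of mean shares were 45.4, with 1 of 3 control libraries above 0, and 13.4. Single libraries carried much of this. For TRAV7N-4 the ratio at D4 was 7.81 without BGB-283 D4 replicate 1 (4.30%), and BGB-283 D4 replicate 3 (0.00494%) lay below control D4 replicate 3 (0.107%). For TRAV14D-2 it was 2.96 at D4 without BGB-283 D4 replicate 2 (2.72%), and the bound at D11 was 11.2 without BGB-283 D11 replicate 2 (0.455%). In BGB-283 D4 replicate 2 the joint name TRAV14-2V14N-2 took 55.1% of TRA counts. In BGB-283 D11 replicate 3 that name took 26.6% while TRAV14D-2 took 0.0199%. Whether reads of the joint name were assigned to TRAV14D-2 was not tested. TRAV7N-4 was also above 0 in 6 of 6 trametinib (0.621% ± 0.320) and 6 of 6 combination libraries (0.478% ± 0.610), without passing (adjusted p = 0.0512 and 0.0912, edgeR). So was TRAV14D-2 (0.0879% ± 0.0433 and 0.183% ± 0.168), without passing either (adjusted p = 0.228 and 0.0912, edgeR). TRAV14D-2 took 0.126% in BGB-283 D4 replicate 3, below 0.207% in control D4 replicate 3. The number of TRAV calls became 0 with a replicate block, with each clonotype counted once, with segments summed to TRAV families and without both shallowest control libraries. It was also 0 without control D11 replicate 1, control D11 replicate 2, BGB-283 D4 replicate 2 or BGB-283 D11 replicate 2, 1 without BGB-283 D4 replicate 1 and 4 without control D4 replicate 3, where the fitted log2 value for TRAV7N-4 moved from 8.54 to 13.2. Many TRAV segments have near-identical copies, so reads may be split between names.

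The combination was compared with each drug alone to ask what the other drug adds. Combination libraries had more TRB clonotypes than trametinib libraries (3355 ± 1473 against 1417 ± 525) and BGB-283 libraries (1031 ± 349; SD, n = 6 each). The 10 largest TRB clonotypes took 48.7% ± 12.03 of TRB counts in combination, 29.8% ± 8.82 in trametinib and 50.2% ± 11.2 in BGB-283 libraries. TRB clonality was 0.346 ± 0.0660, 0.204 ± 0.0634 and 0.330 ± 0.0983 in the same order. The joint segment name TRAV14-2V14N-2 took 2.24% ± 0.753 of TRA counts in combination and 16.8% ± 20.8 in BGB-283 libraries, where BGB-283 D4 replicate 2 reached 55.1%.

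Against trametinib, clonotype number rose 2.25-fold as detected (log2 1.17, p = 0.02, adjusted p = 0.03, exact permutation test, 6 against 6 libraries). The call ended with counts under 20 removed (0.55) and with a replicate block (adjusted p = 0.054, exact permutation test). It did not pass at equal counts (0.89, p = 0.045, adjusted p = 0.054, exact permutation test), though it did with 20 thinning draws (0.90, adjusted p = 0.048), and at equal estimated molecules the difference was 0.04 (adjusted p = 0.88, exact permutation test). TRB counts rose 2.03-fold (log2 1.02, p = 0.01, adjusted p = 0.03, exact permutation test). The 10 largest clonotypes (18.9 points, p = 0.02, adjusted p = 0.06), TRB clonality (0.142, p = 0.015, adjusted p = 0.09) and TRA clonality (0.129, p = 0.01, adjusted p = 0.06) did not pass in exact permutation tests. The clonotype call ended without trametinib D11 replicate 2 (1.01), combination D4 replicate 2 (1.09) or combination D11 replicate 2 (0.93), and the call on TRB counts ended without any 1 of the 6 combination libraries (0.87 to 1.14). At equal counts the clonotype difference passed without trametinib D11 replicate 1 (1.02) or combination D11 replicate 3 (1.13), TRB clonality (0.157) and the 10 largest clonotypes (21.6 points) passed without combination D4 replicate 2, and TRA clonality passed without trametinib D4 replicate 3 (0.141).

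Against BGB-283, clonotype number rose 3.10-fold as detected (log2 1.63) and 2.63-fold at equal counts (log2 1.39), each with p = 0.01 and adjusted p = 0.02 in an exact permutation test of 6 against 6 libraries. The difference at equal estimated molecules (0.59, adjusted p = 0.07), TRB counts (0.86, adjusted p = 0.08), the 10 largest clonotypes (-1.48 points, adjusted p = 0.965, with -6.15 at D4 and 3.19 at D11) and TRB clonality (0.0158, adjusted p = 0.75, negative with a Simpson-based index and in estimated molecules) did not pass in exact permutation tests. TRAV14-2V14N-2 fell by 2.84 on the log2 scale (SE 0.678, adjusted p = 0.0363, edgeR). This call ended with a replicate block (-2.82) and with each clonotype counted once (-0.65), and TRAV families gave 0 calls. It also ended without BGB-283 D4 replicate 2 (-1.84), BGB-283 D11 replicate 3 (-2.07) or any 1 of the 6 combination libraries (-2.96 to -2.68), and the number of TRAV calls became 2 without BGB-283 D4 replicate 1. The clonotype call as detected ended without combination D11 replicate 2 (1.39, adjusted p = 0.05), and TRB counts passed without BGB-283 D4 replicate 2 (1.00) or BGB-283 D11 replicate 3 (1.10). Of the fixed lists 0 of 4 passed against trametinib (iNKT alpha -0.79, partner betas -0.24, Vbeta8 -0.16, adjusted p = 0.75 each) and 0 of 4 against BGB-283 (1.57, 0.32 and 0.47, adjusted p = 0.553, 0.615 and 0.553) in exact permutation tests.

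**Figure D4:**
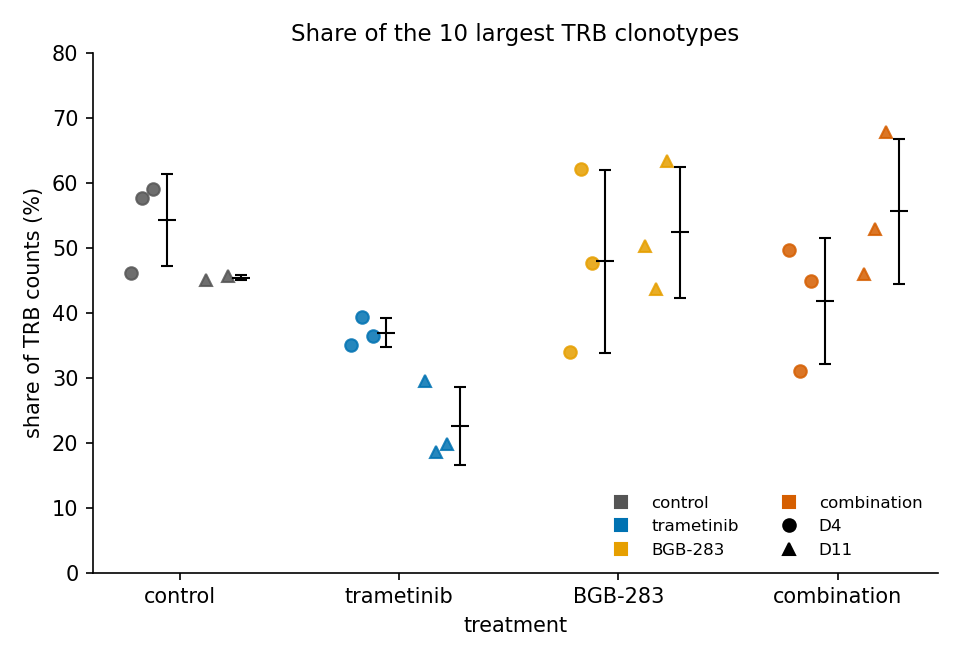
Share of TRB counts (percent) held by the 10 largest TRB clonotypes of each library, by treatment and day; points are libraries and black bars the mean ± SD of each group. The 6 trametinib libraries lie between 18.6% and 39.4%, below the lowest control library at 45.1%.

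D11 was compared with D4 to ask whether the repertoire moved with time. No measure taken per library passed. TRB clonotype number differed by -0.22 on the log2 scale (adjusted p = 0.482) and by -0.15 at equal counts (adjusted p = 0.600, positive in estimated molecules), TRB counts by -0.50 (adjusted p = 0.135) and the 10 largest clonotypes by -1.23 points (adjusted p = 0.965). TRB clonality differed by -0.0289 (adjusted p = 0.522) and TRA clonality by -0.0364 (adjusted p = 0.333). These were permutation tests of 11 against 12 libraries, stratified by treatment. Within single treatments the differences had both signs: the share of the 10 largest clonotypes differed by -8.89 points in control, -14.3 in trametinib (p = 0.1, the smallest possible, exact permutation test), 4.46 in BGB-283 and 13.8 in combination libraries. TRB clonotype number differed by 0.26, 0.27, -0.49 and -0.91 on the log2 scale and TRB clonality by -0.0772, -0.0915, -0.0115 and 0.0646 in the same order. No treatment contrast differed between the days past the threshold in these measures (adjusted p from 0.25 to 0.695, from 0.944 to 0.975 and from 0.463 to 0.88, exact permutation tests). Such p-values refer to no treatment effect on either day, so they do not show equal effects. The log2 odds of iNKT alpha, whose size depends on the 0.5 counts added, differed by 2.53 (p = 0.0315, adjusted p = 0.126 over 4 lists, permutation test), those of the partner betas by -0.06 and of Vbeta8 by -0.24 (adjusted p = 0.838 and 0.759); iNKT alpha passed without BGB-283 D4 replicate 1 (3.07) or combination D11 replicate 3 (2.99).

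Segment usage by day gave 0 calls in edgeR for TRBV, TRAV and TRBJ, with 4, 12 and 5 segments under an unadjusted p of 0.05 and 3, 12 and 4 calls in DESeq2. The TRBJ segments with the smallest p were TRBJ1-3 (log2 1.08), TRBJ2-3 (-0.86) and TRBJ2-2 (0.93), with adjusted p = 0.0642, 0.0642 and 0.0683 in edgeR. The number of TRBJ calls became 5 without control D4 replicate 1, 2 without BGB-283 D11 replicate 1 or BGB-283 D11 replicate 3, and 1 without control D11 replicate 1, BGB-283 D4 replicate 3 or combination D11 replicate 1.

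TRBV16 was the most used V segment of the beta chain in control (22.3% ± 11.8 of TRB counts, n = 5), trametinib (17.4% ± 4.74) and BGB-283 libraries (28.1% ± 18.7, n = 6 each). In combination libraries TRBV3 (13.7% ± 10.99), TRBV19 (13.4% ± 13.7) and TRBV16 (12.9% ± 5.80) were close to each other. In edgeR 0 of 24 TRBV and 0 of 12 TRBJ segments passed in any of the 5 treatment contrasts. In the order combination, trametinib and BGB-283 against control, then combination against trametinib and against BGB-283, 0, 2, 3, 1 and 2 TRBV segments had an unadjusted p under 0.05, and DESeq2 called 1, 1, 4, 2 and 0. For TRBJ these numbers were 0, 0, 0, 1 and 2, and DESeq2 called 0 in each. The TRBV segments with the smallest p were TRBV12-2 (log2 -1.08), TRBV26 (1.70), TRBV19 (1.33), TRBV5 (1.84) and TRBV16 (-1.10) in that order, with adjusted p = 0.518, 0.294, 0.261, 0.303 and 0.446. A single TRBV call appeared for trametinib and for BGB-283 against control without control D4 replicate 1, and for BGB-283 without control D11 replicate 2.

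For TRAV, edgeR called 0 of 118 segments for combination against control, trametinib against control and combination against trametinib, with 16, 15 and 6 under an unadjusted p of 0.05 and 13, 11 and 5 calls in DESeq2. For BGB-283 against control and combination against BGB-283, with 2 and 1 calls in edgeR, 17 and 9 segments had an unadjusted p under 0.05 and DESeq2 called 14 and 3. Combination against control gave 7 calls without control D4 replicate 3 and 1 without control D4 replicate 1. Trametinib against control gave 4 without control D4 replicate 3, 2 without control D4 replicate 1 and 1 without control D4 replicate 2. The contrasts with control share the same 5 control libraries, so part of any likeness between them may come from those controls. In simulated data for combination against control a 16-fold rise was called in 75% of changed TRBV, 7% of changed TRAV and 100% of changed TRBJ segments. Only segments below the median share were changed, so these values do not cover falls or commoner segments.

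Mean TRB CDR3 length, each clonotype counted once, was 13.97 ± 0.176 residues in control (SD, n = 5), 13.99 ± 0.0881 in trametinib, 13.96 ± 0.0367 in BGB-283 and 13.95 ± 0.0766 in combination libraries (SD, n = 6 each). None of the 6 contrasts passed in permutation tests, with adjusted p from 0.795 to 0.98, though combination minus control was 0.132 residues at D4 and -0.215 at D11, with D11 minus D4 at 0.296 in control and -0.0506 in combination libraries. TRA clonality did not pass against control for combination (0.0773, adjusted p = 0.32), trametinib (-0.0514, adjusted p = 0.333) or BGB-283 (0.0875, adjusted p = 0.32), or for combination against BGB-283 (-0.0102, adjusted p = 0.845), in exact permutation tests.

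Single clonotypes reached large shares in many libraries. The Wilson intervals given here take every count as independent. Several counts may come from 1 molecule, so the intervals are too narrow for the sampling of molecules. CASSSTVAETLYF (TRBV16, TRBJ2-3) took 43.6% of TRB counts in BGB-283 D4 replicate 2 (95% Wilson interval 43.4% to 43.8%), and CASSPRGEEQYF (TRBV12-1, TRBJ2-7) took 30.8% in control D4 replicate 3 (30.60% to 31.02%). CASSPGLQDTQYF (TRBV16, TRBJ2-5) took 25.04% in control D4 replicate 2 (24.8% to 25.3%). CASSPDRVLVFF (TRBV19, TRBJ1-1) took 24.1% in combination D11 replicate 3 (23.9% to 24.3%) and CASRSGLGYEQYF (TRBV3, TRBJ2-7) took 21.6% in combination D11 replicate 2 (21.5% to 21.8%). In trametinib libraries the highest was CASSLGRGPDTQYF (TRBV3, TRBJ2-5) at 14.5% in trametinib D4 replicate 1 (14.2% to 14.7%).

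Few TRB clonotypes recurred between libraries. Of 35389, 1351 (3.82%) were found in at least 2 libraries, 37 in at least 5 and 8 in at least 8. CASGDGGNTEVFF (TRBV13-2, TRBJ1-1) was found in 15 libraries, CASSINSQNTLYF (TRBV19, TRBJ2-4) in 13, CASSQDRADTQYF (TRBV2, TRBJ2-5) and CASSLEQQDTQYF (TRBV12-2, TRBJ2-5) in 12 each and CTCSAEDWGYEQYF (TRBV1, TRBJ2-7) in 9. TRA clonotypes recurred more often, with 2477 of 29047 (8.53%) in at least 2 libraries. Morisita-Horn similarity of TRB repertoires, which weighs shared clonotypes by their shares, was 0.0136 over 22 same-group pairs and 0.00682 over 231 other pairs (difference 0.00675, p = 0.135, permutation test). The Jaccard index after thinning, which counts presence alone, was higher within groups (0.00400 against 0.00299, p = 0.00034, permutation test). Thinning made counts equal but not clonotype numbers, which differed between treatments. The index depends on those numbers, so their likeness within groups could raise it, which was not tested. The Morisita-Horn difference passed without BGB-283 D4 replicate 3 (0.00919, p = 0.0363) and turned negative without combination D11 replicate 1 (-0.000486, p = 0.904) in the same permutation test.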

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

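The tests of explanations weighed here were chosen only after the results they address were seen.

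Some differences from control were unlike at D4 and D11, by a test of the difference between days. In the permutation tests treatment labels were shuffled within each day, so the p-values refer to no treatment effect on either day. Among the measures and lists so tested CDR3 length alone passed, and no adjustment covered the number of measures. TRB CDR3 length differed by -0.346 residues between the days for combination against control (0.132 at D4 and -0.215 at D11, p = 0.01, adjusted p = 0.0375, exact permutation test). For BGB-283 against control it differed by -0.301 residues (0.1101 at D4 and -0.191 at D11, p = 0.015, adjusted p = 0.0375, exact permutation test), and for trametinib by -0.244 without passing (adjusted p = 0.1, exact permutation test). Most of this lay in the control libraries, where D11 minus D4 was 0.296 residues, against -0.0506 in combination, -0.00490 in BGB-283 and 0.0515 in trametinib libraries. In edgeR the log2 fold at D11 minus that at D4 was -5.11 for TRAV16D/DV11V16N (adjusted p = 0.0252) and 7.97 for TRAV7N-5 (adjusted p = 0.0252), both for trametinib against control. For TRBJ2-2 it was -4.21 for combination (adjusted p = 0.00534) and -3.41 for trametinib (adjusted p = 0.0440) against control. These contrasts use the same 5 control libraries, and the control values differed between days: TRBJ2-2 took 21.4% of TRB counts in control D11 replicate 1, where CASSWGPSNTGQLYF (TRBV16, TRBJ2-2) held 17.6%. TRAV16D/DV11V16N reached 16.1% of TRA counts in a control D11 library and TRAV7N-5 reached 11.2% in a control D4 library.

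More TRB clonotypes were found at equal counts in trametinib and combination than in control libraries. For trametinib, greater depth in counts is argued against by 8 of 8 pairs in which a trametinib library no deeper than a control library held more clonotypes. These pairs share libraries, most of all control D4 replicate 3, and mix the days, so they are not independent. For the combination, the difference was 2.47 at equal counts (adjusted p = 0.02, exact permutation test), against 2.79 as detected. This argues against unequal counts alone as the whole cause. Molecules that hold many counts mostly survive such thinning, so it does not equalise molecules. Greater depth in molecules therefore stays open for the combination. Fewer counts per molecule in treated libraries stays open for both, and in combination libraries for their excess over trametinib libraries (0.89 at equal counts). The differences at equal estimated molecules do not decide, since that estimate assumes 20 counts per molecule in every library while the share of low counts at exactly 20 was on average 33.5% in control and 4.99% in combination libraries, with the trametinib mean between. Pairs in which the library from the group with more clonotypes had a share at 20 no lower than the other numbered 0 for combination against control, 0 for combination against trametinib and 8 for trametinib against control. In 7 of these 8, from 3 trametinib libraries, the treated library held more clonotypes at equal counts, which is too few to decide. A larger or more diverse T cell infiltrate stays open as a biological explanation, as do unequal amounts of T cell RNA, and neither was tested.

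The canonical iNKT alpha CDR3 was listed at 0 in 3 of 5 control libraries and above 0 in 18 of 18 treated libraries. Too few TRA molecules is argued against for control D4 replicate 3, where 46.2 estimated molecules were expected at the treated median share of 0.396%. In control D4 replicate 1 and control D11 replicate 1 the numbers expected were 9.50 and 7.97. Treated shares went down to 0.0766%, at which far fewer would be expected, so too few molecules stays open there. These numbers also treat molecules as independent. Outside each library's 10 largest TRA clonotypes the treated median share was 0.679%. At that share the numbers expected outside them in these 3 libraries ran from 8.60 to 32.5 estimated molecules. Dilution by large TRA clones is argued against at this median share alone, and stays open at lower shares. A lower share of iNKT cells in control samples may explain the pattern, as may differences in sampled tissue, which were not tested. All treated groups are compared with the same 5 control libraries.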

How the results depend on the processing

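The alternatives chosen after seeing the data were estimated molecules, removal of counts under 20, leaving out both shallowest control libraries, TRAV11N included, TRAV families, 20 draws, adjustment over 10 lists and every test of TRB counts. Outside the runs that leave out 1 library, 378 of 454 values that answer a comparison kept their direction and side of the threshold, or stayed near the value reported, and 120 of 137 for single lists and segments did. These totals include settings that could not change a value, so they overstate stability. Such settings were removal of counts of 1 and, for the beta lists, TRAV11N included. Where they did not, the cause was not tested, except that leaving out libraries leaves fewer permutations. Contrasts are named below by treatment alone when against control. Not run were nucleotide clonotypes, out-of-frame entries and the gamma and delta results, for which the table has no entries; removal of counts of 1 removes nothing.

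With a Simpson-based index the result "TRB clonality: combination vs control" was -0.0236, "TRB clonality: combination vs BGB-283" was -0.0339 and that for trametinib was -0.103, the last now past the threshold. In estimated molecules they were -0.0154, -0.0281 and -0.103, clonotypes at equal depth were 0.59 for combination against BGB-283 and 0.0921 for D11 against D4, the top 10 share was -0.295 for BGB-283, TRB counts were 0.96 for combination against BGB-283, 2 TRAV segments passed there and 1 list passed for trametinib. Without thinning clonotypes passed for BGB-283 (1.16) and combination against trametinib (1.17), and with 20 draws they passed too (1.07 and 0.90). With counts under 20 removed, clonotypes detected were 0.86 for BGB-283 and 0.55 for combination against trametinib, and CDR3 length was 0.0118 for combination against BGB-283. With a replicate block, clonotypes were 1.02 for BGB-283 and, as detected, 1.17 for combination against trametinib (adjusted p = 0.054). The block also gave -0.589 for "TRB top 10 share: BGB-283 vs control", TRB counts of 0.85 for BGB-283 and 0.86 for combination against BGB-283, CDR3 length of 0.00291 for trametinib, and 0 TRAV calls for BGB-283 and for combination against BGB-283.

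Without both shallowest control libraries, clonotypes at equal counts were 1.93 for combination and 1.04 for trametinib, clonotypes detected were 2.24, 1.07 and 0.61 for combination, trametinib and BGB-283, TRB counts 1.20 for combination, "TRB top 10 share: trametinib vs control" -22.3 and that for BGB-283 -1.85. The same setting gave 2, 3 and 2 TRBV calls for combination, trametinib and BGB-283, 1, 1 and 0 TRAV calls, 2 TRBJ calls by day and 0 lists for trametinib. Lists passing for trametinib became 1 with 5 counts added and 0 adjusted over 10 lists; with TRAV11N 1 passed for combination, and iNKT alpha was 0.14 for combination against trametinib. With each clonotype counted once, Vbeta8 was 0.0712 for combination against trametinib and "list iNKT partner betas: D11 vs D4" was 0.0448. That setting gave 3, 3 and 1 TRBV calls for combination, BGB-283 and combination against BGB-283, 0, 1 and 0 TRAV calls for BGB-283, combination against trametinib and combination against BGB-283, and 2 TRBJ calls by day. TMM factors gave 1 TRBV call for combination against trametinib and 2 TRBJ calls by day. No filter gave 1, 1, 5, 2 and 1 TRAV calls for combination, trametinib, BGB-283, combination against BGB-283 and by day, and TRAV families 0, 0 and 2 for BGB-283, combination against BGB-283 and by day. DESeq2 gave TRBV 1, 1, 4, 2 and 3 calls for combination, trametinib, BGB-283, combination against trametinib and by day, TRAV 13, 11, 14, 5, 3 and 12 with combination against BGB-283 before by day, and TRBJ 4 by day. The Jaccard difference was 0.00102 (p = 0.00034, permutation test).

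Leaving out 1 library at a time gave ranges as follows for results that changed. Clonotypes at equal counts ran from 2.14 to 2.80 for combination, 1.25 to 1.90 for trametinib, 0.75 to 1.40 for BGB-283, 0.69 to 1.13 for combination against trametinib and -0.31 to 0.0153 by day. Clonotypes detected ran from 2.46 to 3.12, 1.29 to 1.95 and 0.83 to 1.49 for the treatments in the same order, and from 0.93 to 1.43 and 1.39 to 1.89 for combination against trametinib and BGB-283. TRB counts ran from 1.52 to 2.16 for combination and from 0.83 to 1.18 and 0.68 to 1.10 against trametinib and BGB-283. The top 10 share ran from -4.22 to 1.56, -22.1 to -18.9 and -3.23 to 3.82 for the treatments, 15.8 to 21.6 and -4.97 to 2.08 for combination against trametinib and BGB-283, and -2.98 to 0.544 by day. TRB clonality ran from -0.108 to -0.0623 for trametinib, 0.127 to 0.160 and -0.0174 to 0.0510 for combination against trametinib and BGB-283, and TRA clonality from 0.112 to 0.148 and -0.0361 to 0.0243 there. CDR3 length ran from -0.0417 to 0.0157 for trametinib, -0.0538 to 0.000428 and -0.0242 to 0.0300 for combination against trametinib and BGB-283. Sharing ran from -0.000486 to 0.00919.

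Vbeta8 ran from -0.0411 to 0.22 for BGB-283 and -0.59 to 0.18 for combination against trametinib, partner betas from -0.31 to 0.14 by day, -0.73 to 0.16 and -0.18 to 0.72 for combination against trametinib and BGB-283, and iNKT alpha from -1.42 to 0.11 for combination against trametinib. For combination, iNKT alpha ran from 2.17 to 5.53, partner betas from 0.21 to 1.11 and Vbeta8 from 0.13 to 0.89. For trametinib they ran from 2.96 to 6.33, 0.82 to 1.07 and 0.58 to 0.85. By day iNKT alpha ran from 1.69 to 3.38. For BGB-283, TRAV7N-4 ran from 7.28 to 13.2 and TRAV14D-2 from 6.61 to 8.86. TRAV14-2V14N-2 ran from -3.08 to -1.84 for combination against BGB-283. Lists passing ran from 0 to 3 for combination and for trametinib and 0 to 1 by day. TRBV calls ran from 0 to 1 for trametinib and BGB-283, TRAV calls from 0 to 7, 0 to 4 and 0 to 4 for the treatments and 0 to 2 for combination against BGB-283, and TRBJ calls from 0 to 5 by day.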

Other observations

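The test of junction length was set before its result was seen, and the tests of spill-over, near-identical clonotypes and other splits of the libraries were chosen only after the results they address were seen.

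Large TRB clonotypes used V segments unevenly. Of clonotypes at 1% or more of a library's TRB counts, 21.7% ± 11.5 used TRBV16, against 15.5% ± 2.34 of all TRB clonotypes (SD over 23 libraries), and the share was higher among the large ones in 14 of 23 libraries. TRBV3 took 13.2% ± 8.14 against 9.69% ± 1.43, higher in 17 of 23. TRBV29 took 3.16% ± 5.41 against 13.1% ± 2.56, higher in 2 of 23. These shares were not tested.

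Large clonotypes of different libraries often resembled each other. Among 274 TRB clonotypes at 1% or more there were 65 cross-library pairs with the same V, J and length and at most 1 mismatch, 23 of them identical, in 21 libraries, and 62 of the pairs joined different groups. A family on TRBV13-3 and TRBJ2-5 (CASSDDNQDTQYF, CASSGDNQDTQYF, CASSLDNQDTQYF and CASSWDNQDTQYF) spanned 5 libraries. On TRBV16 and TRBJ2-5, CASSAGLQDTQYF, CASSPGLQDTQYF and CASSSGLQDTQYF were 1 mismatch apart. They were found at 1% or more in control D4 replicates 2 and 3, trametinib D4 replicate 2 and combination D11 replicate 3. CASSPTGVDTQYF on the same segments is not near-identical to these and paired only with itself, in other libraries. The most alike libraries were BGB-283 D4 replicate 3 and combination D11 replicate 2 (Morisita-Horn 0.505, 43 shared clonotypes), then combination D11 replicates 1 and 2 (0.178, 37 shared). A single clonotype, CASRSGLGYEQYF (TRBV3, TRBJ2-7), took 13.0% of TRB counts in BGB-283 D4 replicate 3. It took 21.6% in combination D11 replicate 2 and 4.51% in combination D11 replicate 1. The index weighs clonotypes by their shares, so these values need not reflect broad overlap. Combination D4 replicate 3 and combination D11 replicate 2 shared more clonotypes, 52, with an index of 0.0913.

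For 259 of the large clonotypes with rarer clonotypes to draw from, 64 such pairs were found, against a mean of 1.72 and a highest value of 9 in random draws of rarer clonotypes of the same library, V and J (p = 0.001, the smallest these draws can give, permutation test). The draws matched neither length nor recurrence, and identical sequences in different libraries had been seen before. Spill-over of reads between libraries as a general cause of recurrence is argued against, since 67.3% of the 171 TRB clonotypes with a highest count of at least 2450 were in 1 library only. Easily recombined junctions stay open: clonotypes in 5 or more libraries were shorter by a difference of -0.390 residues (13.62 against 14.01, p = 0.119, permutation test), which does not decide. A shared antigen may also select such families, which was not tested.

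Splits of the same libraries into groups of the same sizes within strata were used to ask whether chance could give as many called segments, with the real one included, 100 splits for the contrasts with calls (raised from 50 after those were seen) and 50 for the others. For TRAV in BGB-283 against control, 6 of 100 splits gave at least the 2 calls found, and the highest other split gave 3, so chance could not be excluded. For TRAV in combination against BGB-283, 2 of 100 gave at least the 1 call found, under a share of 0.05 for this contrast taken alone. The only other such split gave 2 calls, more than the real one, the share is not adjusted for the other contrasts, and the call ended under several alternatives, so it is weak ground against chance. For contrasts with 0 calls the test decides nothing, since every split gives at least 0; their highest other split gave at most 3 calls.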
